A study of Homo sapiens with 8 samples.

How the data were processed

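The samples were RNA from OCI-AML3 cells grown with or without 1 µM retinoic acid for 2 h or 4 h. Per the labels' protocols, polyA RNA was purified with poly-T beads, fragmented, copied from random hexamers and made into libraries that do not keep the strand. The series design text speaks of independent experiments, and p-values of single genes here reflect the spread between these libraries. List p-values by camera at the preset correlation compare the genes of a list with the other genes, and do not measure that spread alone.

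The deposited values are whole-number counts per gene, in one table with a column per library, as featureCounts writes it. Per the submitters' processing notes the tools were FastQC 0.12.1, HISAT2 2.2.1 and featureCounts 2.0.6, with the genome build hg38. The counting options and the annotation release are not given in the sources used here. The table has 61471 rows named by gene symbol or, for 20434 rows, by Ensembl identifier, and 22798 rows hold at least 1 count. The exons of 73 symbols lie on more than 1 chromosome, so those rows join separate genes. Without strand, reads from overlapping or antisense genes cannot be told apart, and reads of near-identical copies could be split or dropped. The exon coordinates in the table gave the bases that each named gene shares with others. Shares over 25% among genes named in the text were found for SENP3 (41.7%, with SENP3-EIF4A1), IL24 (41.6%, with FCMR), IER3 (38.9%), NFE2L2 (38.4%), LYZ (34.7%), HIC1 (29.8%), HOXA9 (27.0%) and CYP26A1 (25.3%). Levels of NCF1 and the histone genes carry the further uncertainty of near-identical copies.

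Groups were taken from the sample titles, which match the library names. The treatment field of the labels contradicts the titles for 6 of the 8 samples. The second RA 2 h library bears the number 3 in the count table and 2 in the labels, so its column was assigned to its group only, and it is called replicate 3 here. The batch field holds one value for all samples. No sample was regrouped from its values. Replicates of each group were compared by a chi-square test of their counts over genes, and the smallest statistic was 4.96 per degree of freedom, so no library was treated as a repeat of another. Library totals ran from 13790273 to 18799953 counts.

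The design of each test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from 4 alternatives chosen after seeing the data: leaving out both RA libraries numbered 3, a replicate block with the number in the labels, leaving out mitochondrial genes, and leaving BTG2 out of the RA receptor target list. Tests of explanations (RA target induction, exchanged labels, separate handling and gene span) were also chosen after seeing the data, as was the bound set for the treatment field, whose grouping was planned. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough counts by filterByExpr were kept (13297), TMM factors computed, and all 8 libraries fitted in one quasi-likelihood model with a mean for each group (glmQLFit, glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes, and a mean is followed by its SD.

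Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 22 lists with at least 5 tested members. An estimated correlation and fry, whose directional p tests whether the genes of a list move one way on balance, were run beside it. List members were also adjusted over the list alone. The 25 lists cover RA receptor targets, retinoid metabolism and transport, the SUMO pathway, p53 targets, NRF2 and antioxidant genes, phagocyte NADPH oxidase, the HOX and MEIS programme, primary granule and progenitor genes, late myeloid maturation, ribosome biogenesis, proliferation and mitosis, interferon-stimulated genes, the integrated stress response, immediate early genes, NF-kB targets, apoptosis regulators, mitochondrial mRNAs, hypoxia and glycolysis, heat shock, cholesterol synthesis, LXR and PPAR targets, histones, and markers of erythroid, lymphoid, and epithelial or fibroblast cells. Some genes stand in more than 1 list, such as BTG2 (RA receptor targets and immediate early genes) and DHRS3 (RA receptor targets and retinoid metabolism). No list median changed when genes at 0 counts in a group were set to the bound of the floor.

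Named genes were chosen by a fixed rule. For each comparison with untreated it takes the 10 largest rises and 10 largest falls by log2 fold change among genes with adjusted p under 0.05, a mean of at least 2 CPM in the higher group, a gene symbol, and every RA library beyond every untreated library. It adds up to 4 called members of each list by smallest p. Always included were CYP26A1, DHRS3, RARA, RARB, RARG, RXRA, NPM1, SENP3, CDKN2A, MDM2, CDKN1A, PML, MYC, HOXA9, MEIS1, ITGAM, CD38, NFE2L2, HMOX1 and TXN. Some genes that the rule takes are not reported here. For 4 h against 2 h it takes 5 rises and 5 falls, of which there were 0. A few further genes are named as the exception within a list (PCNA) or to show the levels between times (MKI67), and were chosen after their values were seen.

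A fold against a group at 0 counts is given as a lower bound, with a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio has an exact 95% binomial interval. These bounds and intervals cover counting error only. The overlap of calls was set beside independent lists and beside 20 simulated sets in which all 8 libraries were drawn around the untreated means with the fitted dispersions. The plan had been to keep the real untreated libraries and draw the RA libraries alone. That was changed after its result was seen, since RA libraries drawn around the mean of those same untreated libraries do not carry the deviation that a shared control adds. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, a robust dispersion prior, other filters, only the groups compared, a replicate block, a fold minimum, thinning to one total, and leaving out each library. The procedure was tested on simulated counts with 200 changed genes per comparison. At 2-fold it recovered 54% of the changed genes at 2 h, 58% at 4 h and 48% between 2 h and 4 h, and at 4-fold 85%, 74% and 77%, with 7, 12 and 13 false calls among 12887, 12904 and 12881 genes.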

Results

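Polyadenylated RNA was measured in OCI-AML3, a human acute myeloid leukaemia line that carries the NPM1 mutation known as NPM1c, with or without retinoic acid (RA) at 1 µM. RA is the ligand of the nuclear receptors RARA, RARB and RARG, and the series title places its action on an axis of mutant NPM1, reactive oxygen species, the SUMO protease SENP3 and ARF, a product of CDKN2A. The 8 libraries fell into 3 groups by their titles: 3 labelled untreated, 2 labelled RA 2 h and 3 labelled RA 4 h. Total gene counts lay between 17135579 and 18799953 in 7 libraries, and RA 4 h replicate 3 held 13790273. Counts were found for 17201, 17878 and 17520 genes in the libraries labelled untreated and for 16212 to 16510 genes in RA 2 h replicate 1 and RA 4 h replicates 1 and 2. The 2 RA libraries numbered 3 in the count table had fewer, 14004 genes at 2 h and 14869 at 4 h. Mitochondrial transcripts took 43.5% of the counts of untreated replicate 1 and 22.9% to 31.6% of the counts of the other 7 libraries. The first principal component held 68.1% of the variance and set the 3 libraries labelled untreated apart from all 5 labelled RA. Correlations of log2 levels across genes, which are not independent replicates, were 0.865 to 0.890 between untreated and RA libraries. They were 0.983 to 0.986 among the untreated libraries and 0.964 to 0.982 within RA 4 h. The 1 pair within RA 2 h had 0.957, and pairs of RA 2 h and RA 4 h libraries had 0.943 to 0.981. RA 2 h replicate 1 correlated better with RA 4 h replicates 1 and 2 (0.981 and 0.980) than with RA 2 h replicate 3.

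Whether the labelled treatment showed in genes that RA receptors are known to switch on was examined first, since a treatment field in the sample labels contradicts the title for 6 of the 8 samples. The libraries labelled RA did not carry more transcripts of these genes. CYP26A1, the RA-degrading hydroxylase, had 0 counts in each of the 8 libraries, and RARB had 0 to 9 counts per library. DHRS3, a retinal reductase that RA induces in many cells, was at 24.1 ± 0.561 CPM (counts scaled to the library total; SD, n = 3) in the untreated libraries, 6.83 ± 1.22 (SD, n = 2) at 2 h and 7.67 ± 0.641 (SD, n = 3) at 4 h. Of the 17 tested RA receptor target genes, 1 was higher and 8 were lower at each time, with the same counts when adjusted over the list alone. Those lower at both times included BTG2 and HIC1, which p53 also induces, and ASB2. BTG2 alone held 265 of the 460 CPM of the list in untreated libraries, and without it the summed level was 195 ± 3.37 CPM (SD, n = 3) there, 142 ± 10.7 (SD, n = 2) at 2 h and 148 ± 9.82 (SD, n = 3) at 4 h. The list was lower as a set by camera (adjusted p = 0.00676 at 2 h and 0.0049 at 4 h), with adjusted p = 0.051 and 0.062 with an estimated correlation. Without BTG2, an alternative chosen after seeing the data, 7 of 16 members were still lower and 1 higher at each time, but the set did not pass (camera adjusted p = 0.090 and 0.097). Without untreated replicate 1, 5 members were lower at 4 h. Because these values go against the labels, groups are called by their labels throughout, and "higher" and "lower" mean in the libraries labelled RA relative to those labelled untreated.

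**Figure D1:**
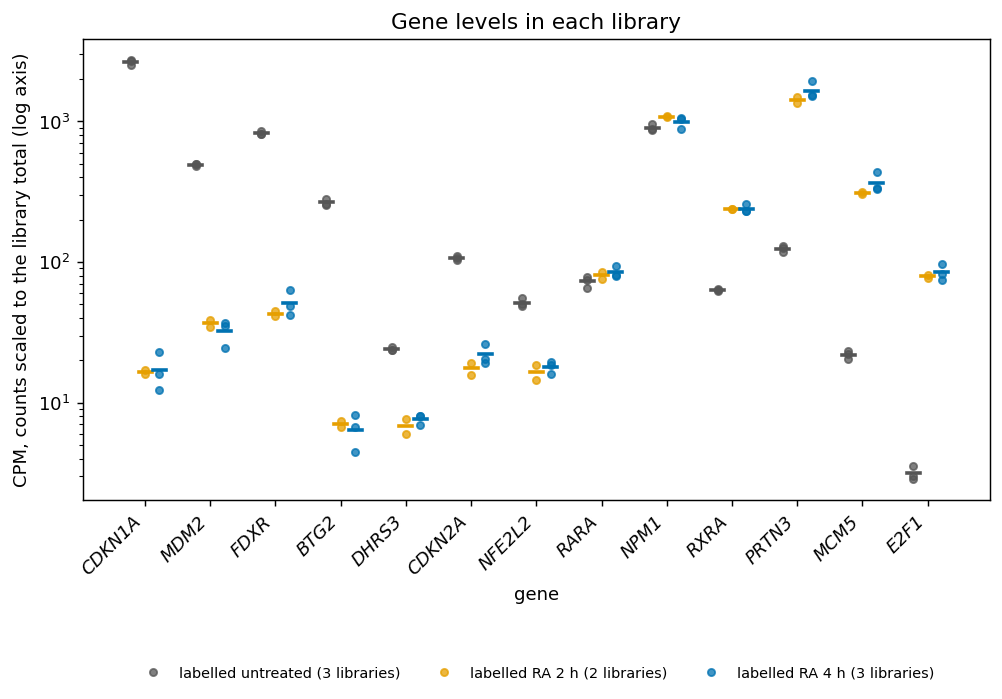
CPM, counts scaled to the library total, on a log axis for 13 genes in the 8 libraries, with a point for each library and a bar at the group mean (grey, labelled untreated; orange, labelled RA 2 h; blue, labelled RA 4 h). CDKN1A lies near 2640 CPM in the untreated libraries and near 17 in those labelled RA, E2F1 goes from 3.14 to 79.0 and 84.3, and RARA and NPM1 lie close together in all groups.

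The comparison at 2 h asked which transcripts RA changes early in these cells. The libraries labelled RA 2 h held far fewer transcripts of p53 target genes and far more of the genes that drive DNA replication and mitosis. CDKN1A, which encodes the cell-cycle inhibitor p21, was at 2640 ± 99.9 CPM (SD, n = 3) untreated and 16.5 ± 0.777 (SD, n = 2) at 2 h, a log2 fold change of -7.32 ± 0.23 (SE). GDF15, a stress-induced cytokine, was at 609 ± 32.4 and 0.797 ± 0.143 CPM. In the other direction E2F1, a transcription factor of the G1 to S transition, was at 3.14 ± 0.352 and 79.0 ± 2.65 CPM. Of 13297 genes tested, 3082 were higher and 3049 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05), and 3330 of these 6131 differed by at least 2-fold.

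All 24 tested p53 target genes were lower at 2 h, with a median log2 fold change of -3.26, and 24 were when adjusted over the list alone (camera adjusted p = 1.33e-46, and adjusted p = 0.00037 with an estimated correlation). Among them MDM2, the ubiquitin ligase of p53, had a log2 fold change of -3.75 ± 0.16 (SE), with FDXR 19.2-fold, PHLDA3 26.9-fold and GADD45A 65.1-fold lower. Of 31 proliferation and mitosis genes, 29 were higher and 1, PCNA, was lower, both over all genes and adjusted over the list alone, with a median log2 fold change of 2.61 (adjusted p = 2.19e-51, and 0.0055 with an estimated correlation). MCM3 and MCM5, subunits of the replicative helicase, were 10.6-fold and 14.1-fold higher, and BIRC5 9.27-fold. The 10 largest rises held further replication factors: ORC1 was 46.0-fold and CDC6 42.5-fold higher. E2F2 had 717 counts in 2 libraries against 1 count in 3, a ratio of 1127 with a 95% counting interval of 202 to 44563. TRAPPC9, WDR76, TMPO-AS1, LRMDA, MAP2K6 and IL17RE were 55.7-, 44.2-, 43.6-, 59.9-, 45.9- and 43.0-fold higher. IQGAP2 had 75 counts against 1, a ratio of 118 with a counting interval of 20.5 to 4716. The 1 untreated count lay in replicate 2 for E2F2 and in replicate 3 for IQGAP2, and without those libraries they were at least 245-fold and 25.1-fold higher. RA 2 h replicate 3 held 58 of the 75 IQGAP2 counts and 127 of the IL17RE counts, and without it the ratio of IQGAP2 was 54.3 (8.51 to 2269; 179 without RA 2 h replicate 1) and IL17RE was 23.7-fold higher. Without untreated replicate 3 the IL17RE ratio was 87.4 (23.8 to 728), and without untreated replicate 1 WDR76 was 74.4-fold higher.

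Of the 10 genes with the largest falls at 2 h by fitted fold change, 7 had 0 counts in both RA libraries, which gives a lower bound and no rank among them. PRDM1, a transcriptional repressor that acts in lymphoid and myeloid maturation, had 1458 counts over the untreated libraries and 0 at 2 h. It was at least 309-fold lower against a floor of 3 counts over the group. By the same floor PTGS2, the inducible cyclooxygenase, was at least 179-fold lower, TBX2 at least 135-fold, CLCA2 at least 91.4-fold, ACHE at least 89.1-fold, IL24 at least 71.9-fold and AXL at least 53.7-fold. All these bounds shrank with 1 RA library left. This follows by construction, as the floor of 3 counts stays while the depth falls, and the counts left were still 0. Without RA 2 h replicate 1 or 3 the bound was 157 or 152 for PRDM1 and 27.3 or 26.4 for AXL. NECTIN4 had 2 counts against 5512, and PHLDB3 1 against 1237, ratios of 1754 (counting interval 485 to 14486) and 787 (141 to 31117). These counts lay in RA 2 h replicate 1, without which they were at least 594-fold and 133-fold lower, and without RA 2 h replicate 3 the ratios were 863 and 387. IL24 shares 41.6% of its exon bases with FCMR in the count table, so its reads are less certain.

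Immediate early genes, NF-kB target genes and histone genes were lower as groups at 2 h. Of 30 immediate early genes, which respond to stimuli within minutes, 25 were lower and 1 higher (27 and 1 adjusted over the list alone), with a median log2 fold change of -2.61 (adjusted p = 8.32e-22, and 0.0077 with an estimated correlation). IER3, BTG2, JUNB and IER5 were 25.7-, 37.7-, 9.19- and 13.5-fold lower. Of 21 NF-kB target genes, 16 were lower and 0 higher (17 and 0 adjusted over the list alone; adjusted p = 5.29e-09, and 0.0077 with an estimated correlation), among them the cytokine genes IL1B, 8.91-fold, and CXCL8, 13.5-fold. Of 10 histone genes tested 8 were lower (8 adjusted over the list alone; adjusted p = 4.34e-06, and 0.045 with an estimated correlation), H2BC5 by 33.5-fold and H2AC6 by 23.1-fold. Their reads could be split among near-identical copies, and polyA selection recovers only part of histone transcripts.

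Myeloid genes went both ways at 2 h. Of 20 late maturation genes, 10 were lower and 2 higher, with the same counts adjusted over the list alone (adjusted p = 0.0002, and 0.0499 with an estimated correlation). CD14 was 12.4-fold, LYZ, which encodes lysozyme, 12.6-fold and CEBPB 5.63-fold lower. Of 14 primary granule and progenitor genes, 6 were higher and 3 lower, with the same counts adjusted over the list alone (adjusted p = 0.0486, and adjusted p = 0.21 with an estimated correlation). The granule proteases PRTN3, CTSG and ELANE were 11.5-, 3.83- and 2.00-fold higher, and the granule proteoglycan SRGN was 2.55-fold lower. Of 18 genes of the HOX and MEIS programme 6 were higher and 1, HOXA9, was lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.47), with FLT3 5.65-fold, CDK6 4.83-fold and MEIS1 3.19-fold higher and HOXA9 2.13-fold lower.

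Genes of the axis in the series title gave mixed results at 2 h. NPM1 was at 902 ± 51.1 CPM (SD, n = 3) untreated and 1079 ± 7.40 (SD, n = 2) at 2 h, a log2 difference of 0.26 ± 0.11 (SE) with adjusted p = 0.059 (0.0024 to 0.20 over 21 alternatives). SENP3 was at 8.59 ± 0.149 and 6.62 ± 2.45 CPM (adjusted p = 0.25, and 0.035 without RA 2 h replicate 1, in a range of 0.035 to 0.95 over 21 alternatives), and 41.7% of its exon bases also belong to the read-through gene SENP3-EIF4A1. CDKN2A, whose counts join the p16 and ARF transcripts, was 6.07-fold lower at 2 h (107 ± 3.82 and 17.5 ± 2.43 CPM). Of 26 SUMO pathway genes 5 were higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.95). SAE1, a subunit of the SUMO-activating enzyme, was 2.92-fold higher. Of 29 NRF2 and antioxidant genes, 4 were higher and 16 lower (4 and 17 adjusted over the list alone; adjusted p = 0.00031, and adjusted p = 0.051 with an estimated correlation). NFE2L2, which encodes NRF2, was 3.12-fold, HMOX1 59.3-fold, NQO1 4.03-fold and TXN 1.34-fold lower. HMOX1 had 21 counts in RA 2 h replicate 1 and 1 in replicate 3, so that it was 30.9-fold lower without replicate 3 and its ratio was 670 (120 to 26470) without replicate 1. Without RA 2 h replicate 3, 4774 genes differed at 2 h, among them 74.2% of the 6131, and without both RA libraries numbered 3, an alternative chosen after seeing the data, 6800 did. Each of these leaves 1 library in the 2 h group, which is assumed to vary like the other groups.

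The comparison at 4 h asked which transcripts differed after longer treatment. p53 target genes were again lower and replication genes higher. CDKN1A was at 17.1 ± 5.29 CPM (SD, n = 3), a log2 fold change from untreated of -7.28 ± 0.19 (SE), and E2F1 was at 84.3 ± 11.1 CPM. Of 13297 genes, 3370 were higher and 3423 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 3466 of these 6793 differed by at least 2-fold. All 24 tested p53 target genes were lower (24 adjusted over the list alone; median log2 fold change -3.43; adjusted p = 1.19e-49, and 0.00031 with an estimated correlation). TP53INP1 was 88.7-fold, GADD45A 48.9-fold, FDXR 16.2-fold and MDM2 15.3-fold lower. Of 31 proliferation and mitosis genes, 29 were higher and 1 lower, also adjusted over the list alone (median 2.62; adjusted p = 2.6e-45, and 0.0056 with an estimated correlation), with MCM3 9.88-fold, MCM5 16.7-fold and BIRC5 9.67-fold higher.

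Among the largest rises at 4 h were MYBL2, a cell-cycle transcription factor, 44.2-fold higher at 354 ± 84.5 CPM (SD, n = 3), with CDC6 42.4-fold, WDR76 44.01-fold, LRMDA 68.3-fold, TRAPPC9 58.9-fold and CD180 45.5-fold higher. E2F2, FSTL4 and BRME1 each had 1 count over the untreated libraries, against 940, 171 and 97 counts at 4 h, ratios of 1031 (counting interval 185 to 40748), 187 (33.2 to 7448) and 106 (18.6 to 4243). RAD51B, a recombination gene, had 139 counts against 3, a ratio of 50.8 (17.0 to 249). RA 4 h replicate 3 held 84 of these, and the ratio was 27.6 (8.98 to 138) without it, 99.3 without untreated replicate 2 and 32.5 without untreated replicate 3. The 1 untreated count of E2F2 lay in replicate 2 and those of FSTL4 and BRME1 in replicate 3, without which they were at least 224-, 40.0- and 22.7-fold higher. CD180 had a ratio of 123 (21.9 to 4902) without untreated replicate 3, and WDR76 was 74.4-fold higher without untreated replicate 1. Of the 10 largest falls by fitted fold change, 9 had 0 counts in the RA 4 h libraries, which gives lower bounds: ENPP2 was at least 284-fold lower, TBX2 at least 193-fold, KRT17 at least 137-fold, CLCA2 at least 131-fold, SDC1 at least 110.4-fold, IL24 at least 103-fold, MUC5AC at least 97.0-fold, VWCE at least 81.2-fold and HES1 at least 71.1-fold. By the same construction these bounds shrank without RA 4 h replicate 1 or 2, to 182 or 180 for ENPP2. NECTIN4 had 4 counts against 5512, a fitted fold of 1149 (759.6 without RA 4 h replicate 1, and a ratio of 1827 without replicate 3).

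Of 30 immediate early genes 26 were lower and 1 higher at 4 h, also adjusted over the list alone (median log2 fold change -2.64; adjusted p = 1.31e-23, and 0.0056 with an estimated correlation), with IER3 40.0-fold and BTG2 41.4-fold lower. Of 21 NF-kB target genes 17 were lower and 0 higher, also adjusted over the list alone (adjusted p = 2.27e-09, and 0.0056 with an estimated correlation), and CXCL8 was 15.3-fold lower. Of 10 histone genes 7 were lower (7 adjusted over the list alone; adjusted p = 3.36e-06, and 0.023 with an estimated correlation). Of 20 late maturation genes 11 were lower and 3 higher (11 and 4 adjusted over the list alone; adjusted p = 0.00036, and adjusted p = 0.062 with an estimated correlation), with LYZ 16.0-fold lower. The primary granule list was not past the threshold at 4 h (adjusted p = 0.056; 6 higher and 4 lower of 14, also adjusted over the list alone), although PRTN3 was 13.3-fold and CTSG 4.38-fold higher. HOXA9 was 2.69-fold lower and MEIS1 3.03-fold higher.

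NPM1 was at 991 ± 91.2 CPM (SD, n = 3) at 4 h (adjusted p = 0.25, and 0.0044 to 0.52 over 21 alternatives) and SENP3 at 6.71 ± 1.04 (adjusted p = 0.22). CDKN2A was 4.86-fold lower at 21.99 ± 3.79 CPM. RXRA, the partner of the RA receptors, was 3.76-fold higher at 238 ± 16.5 CPM, while RARA, at 84.8 ± 8.10 CPM, and RARG, at 2.65 ± 1.07, did not pass the test (adjusted p = 0.11 and 0.77). MYC was 1.44-fold higher. PML did not pass the test at 4 h (adjusted p = 0.058, and 0.00047 to 0.19 over 21 alternatives) and was 1.37-fold lower at 2 h. CD38 was 1.35-fold lower at 4 h, a call lost without untreated replicate 1 or 2, and did not pass at 2 h (adjusted p = 0.19), and ITGAM, with 16 counts over the 4 h libraries, did not pass (adjusted p = 0.94). Of 29 NRF2 and antioxidant genes 4 were higher and 15 lower, also adjusted over the list alone (adjusted p = 0.00052, and adjusted p = 0.063 with an estimated correlation), with NFE2L2 2.85-fold and HMOX1 23.2-fold lower. Without both RA libraries numbered 3, 8155 genes differed from untreated at 4 h.

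**Figure D2:**
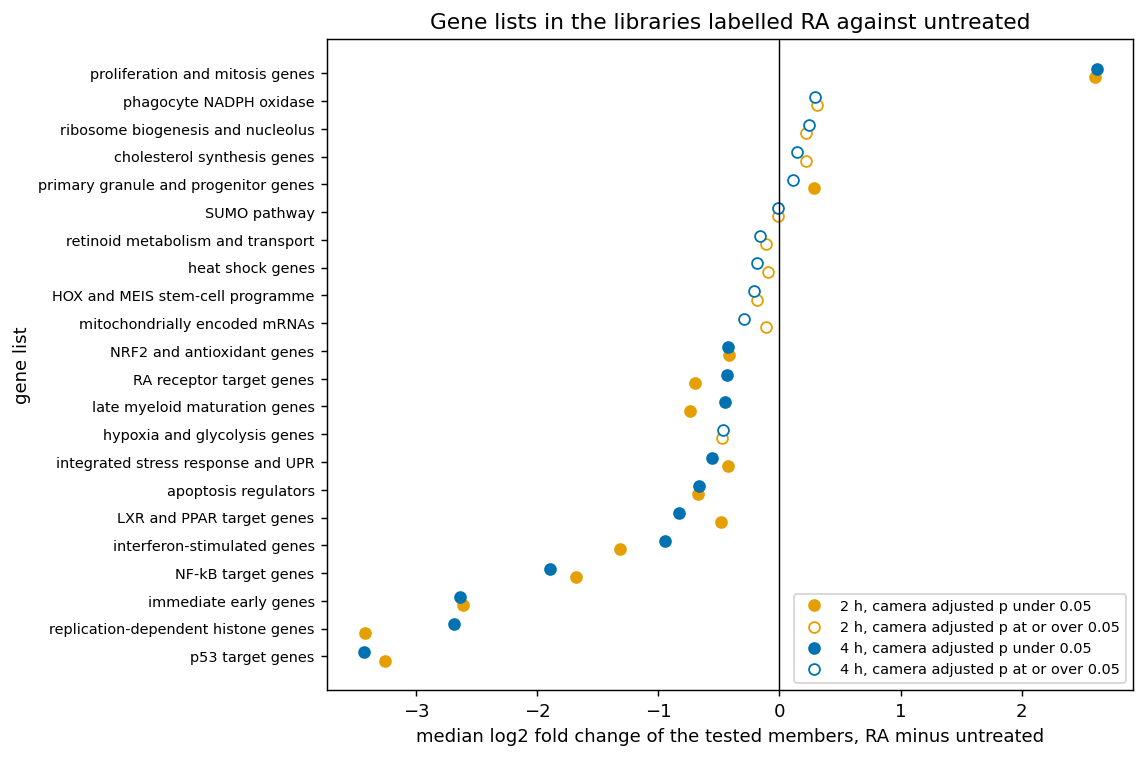
Median log2 fold change of the tested members of 22 gene lists in the libraries labelled RA 2 h (orange) and RA 4 h (blue) against those labelled untreated; filled points mark camera adjusted p under 0.05 with the preset correlation. The proliferation list lies at 2.61 and 2.62, and the p53 target list at -3.26 and -3.43.

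Over all 22 lists tested, 13 passed the threshold at 2 h, 2 higher and 11 lower, and 12 at 4 h, 1 higher and 11 lower. With an estimated correlation 6 and 5 lists passed. At both times these were the p53, proliferation, immediate early, NF-kB and histone lists, joined at 2 h by late maturation.

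The last comparison asked whether the response differed between the times. The levels at 2 h and 4 h lay close together: the log2 difference, 4 h minus 2 h, was 0.04 for CDKN1A (95% interval -0.36 to 0.43), -0.18 for MDM2 (-0.49 to 0.13), 0.10 for MKI67, a proliferation marker (-0.15 to 0.36), 0.17 for DHRS3 (-0.24 to 0.57) and 0.00 for RXRA (-0.21 to 0.21). It was -0.34 for HOXA9 (-0.67 to -0.01), with adjusted p = 0.63. No gene of 13297 passed the threshold by edgeR (smallest adjusted p = 0.10), with 1035 genes at an unadjusted p under 0.05, where 665 are expected by chance. DESeq2 called 9 genes and limma-voom 0. For 8605 genes, 64.7% of those tested, the 95% interval lay within 2-fold in either direction. No list passed the threshold. Adjusted over the list alone, 3 genes passed: the p53 targets TP53INP1, with a log2 difference of -1.09 ± 0.31 (SE), and PPM1D, with 0.75 ± 0.19, and the interferon-induced chemokine gene CXCL10, with -3.25 ± 0.84. These 3 were picked after their values were seen. Without RA 2 h replicate 1, 52 genes passed, and without both RA libraries numbered 3, 4 did, with the 1 library left at 2 h assumed to vary like the other groups.

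Calls at the 2 times overlapped widely. Of the genes called in the same direction in both comparisons, 2813 were higher and 2660 lower, where independent lists of these sizes would share 781 and 785, and no gene was called in opposite directions. Log2 fold changes at 2 h and 4 h correlated across genes at 0.894. Both comparisons used the same 3 untreated libraries: in 20 simulated sets with no changed genes the correlation averaged 0.430 and no gene was called at both times. The covariance of the fold changes was 2.07 against 0.0654 in the simulations. With 3 untreated libraries the controls could not be split, so part of the excess over independent lists may come from the shared controls.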

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

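Apart from the changes given next, the counts at 2 h and 4 h stayed within 1.5 times of their values. Grouping by the treatment field of the labels in place of the titles called 0 genes between RA and untreated, where the titles called 7084. Its untreated group holds only libraries titled RA, and its RA group holds libraries of both titles. A minimum of 2-fold left 3330 genes at 2 h and 3466 at 4 h by its construction. With an estimated correlation 6 lists passed at 2 h and 5 at 4 h. The cause was not tested, but a higher correlation does not account for every loss. The RA receptor target list lost its call at 2 h with an estimated correlation of -0.028, below the preset 0.01. Leaving out each library in turn gave 4774 to 7209 genes at 2 h, 5759 to 7272 at 4 h, 0 to 52 between 2 h and 4 h, 4546 to 6209 shared calls, 12 to 13 lists at each time, and 1 RA receptor target higher and 6 to 8 lower at 2 h and 5 to 8 lower at 4 h. The 52 came without RA 2 h replicate 1. Leaving out either RA 2 h library, or both RA libraries numbered 3, leaves 1 library in that group, assumed to vary like the others. Between 2 h and 4 h DESeq2 called 9 genes, no filter on low counts 40, and leaving out both RA libraries numbered 3 called 4; the cause was not tested. Of 5056 values of named genes under alternatives 4997 kept their direction and side of the threshold, 38 lost and 21 gained the call. No called value changed sign; RARG and ITGAM, not called in either fit, changed sign in 10 cases. The gains and losses included NPM1 (log2 fold change 0.30 at 2 h under the replicate block), PML, CD38, VIM, IL7R and 3 mitochondrial mRNAs. Without RA 2 h replicate 1, SENP3 gained a call at 2 h (log2 fold change -0.83) and MYC lost its call (0.49). Without untreated replicate 1 the calls of MT-ND5 and MT-ND6 were lost at both times and that of MT-CO1 at 2 h but not at 4 h.

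The replicate numbers gave no clear pairing of the libraries. Correlations of deviations from the group means were 0.015 to 0.068 for the 7 pairs with the same number and -0.068 to 0.031 for the 14 others. Not every library correlated best with its own number. All values for the same number were above 0, and the deviations of the 2 RA 2 h libraries mirror each other, so a weak pairing is not excluded. With the replicate block 5848 genes were called at 2 h, 6807 at 4 h and 0 between them, with 5248 shared calls. Depth limits genes with few counts, such as RARB and ITGAM. Thinning to the smallest library total, 13790273 counts, gave 5949 and 6710 calls.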

Other observations

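Of the tests here, those of RA target induction, of exchanged labels, of separate handling and of gene span were chosen after the result was seen, as was the bound for the treatment field. The remaining lists fixed in advance moved less as groups, or lost their call with an estimated correlation. Of 24 interferon-stimulated genes, 12 were lower at each time and 0 and 1 higher (12 and 14 lower, 0 and 2 higher adjusted over the list alone), with TRIM22 19.2-fold and 21.97-fold and IRF7 4.53-fold and 4.44-fold lower (camera adjusted p = 0.0002 and 0.00077, and adjusted p = 0.051 and 0.063 with an estimated correlation). Of 24 integrated stress response genes, 13 and 12 were lower and 4 and 5 higher (14 and 13 lower, 4 and 6 higher adjusted over the list alone; adjusted p = 0.012 and 0.0048, and adjusted p = 0.10 and 0.087 with an estimated correlation). SESN2, DDIT4 and ATF3 were 8.63-, 9.38- and 33.9-fold lower at 2 h (ATF3 54.1-fold without RA 2 h replicate 1), and PHGDH, the first enzyme of serine synthesis, was 8.73-fold and 8.94-fold higher. Of 28 apoptosis regulators 16 were lower at each time and 6 and 5 higher (17 and 18 lower, 6 and 5 higher adjusted over the list alone; adjusted p = 0.0091 and 0.0043, and adjusted p = 0.051 and 0.062 with an estimated correlation). The death receptor gene TNFRSF10B was 10.7-fold and MCL1 3.49-fold lower at 2 h, and BCL2 was 5.46-fold higher. Of 19 LXR and PPAR targets 7 and 8 were lower and 4 and 3 higher (8 and 9 lower, 4 and 4 higher adjusted over the list alone; adjusted p = 0.013 and 0.0069, and adjusted p = 0.066 and 0.062 with an estimated correlation), with PLIN2 11.6-fold, CD36 7.29-fold and PLTP 7.07-fold lower at 2 h.

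At 2 h the lists that did not pass, beside those in the report, were retinoid metabolism (3 higher and 3 lower of 13), phagocyte NADPH oxidase (4 and 2 of 10), ribosome biogenesis (12 and 6 of 31), cholesterol synthesis (8 and 2 of 19), heat shock (2 and 6 of 17), hypoxia and glycolysis (5 and 10 of 21) and mitochondrial mRNAs (0 and 3 of 13). None of these passed at 4 h either, where camera adjusted p ran from 0.13 for hypoxia and glycolysis to 0.92 for retinoid metabolism. FBL, a nucleolar methyltransferase, was 2.85-fold higher, NCF1 3.74-fold lower and the NADPH oxidase subunit gene CYBA 1.72-fold higher at 2 h. Markers of other cell types gave little: 0 erythroid genes had enough counts to be tested, 4 lymphoid genes did, of which TRAC and IL7R were lower at 2 h from 0.851 ± 0.460 and 1.83 ± 0.204 CPM untreated, and at 4 h TRAC, IL7R and CD4 (1.19-fold) were lower. Both calls at 2 h were lost without RA 2 h replicate 3 (adjusted p = 0.13 and 0.105), and those of IL7R at both times and of CD4 without any 1 of the untreated libraries or, at 4 h, without RA 4 h replicate 2. Of the epithelial and fibroblast list VIM was tested and was 1.26-fold lower at 2 h, a call lost without RA 2 h replicate 3 or untreated replicate 1 or 2. Genes outside these lists, such as KRT17 and MUC5AC among the largest falls at 4 h, were not examined as markers of cell type. BOLA2B, which has near-identical copies, had a mean of 34.0 CPM at 2 h, most of it from replicate 3, against 0.658 at 4 h and 1.11 untreated. CDKN2B, beside CDKN2A, was at 42.6 CPM untreated, 0.0869 at 2 h and 0.317 at 4 h. BOLA2B and CDKN2B were picked after their values were seen.

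Many genes, 7084 over both times, set the libraries labelled untreated apart from those labelled RA, with little difference between 2 h and 4 h. The treatment field of the labels does not give this grouping, as it called 0 genes against 7084 for the titles, and an exchange of some labels between untreated and RA libraries is argued against, as 0 of the 8 libraries correlated better with a library of the other side than with one of its own. If the titles are right and the groups differ by RA alone, an induction of RA receptor targets is argued against. Of 17, 8 were lower at 4 h (5 without untreated replicate 1) and 1 higher. The list as a set had camera adjusted p = 0.062 with an estimated correlation, and 0.097 at the preset correlation without BTG2. If the untreated libraries also differ in handling, this cannot be decided, as a fall relative to such a control does not speak on induction. An exchange of all 3 untreated labels with RA labels, as the treatment field would have it, is argued against as the source of this difference. Such an exchange is among the other splits into 5 and 3 given next, of which the highest called 0 genes. As each of those splits mixes the groups by title, this speaks on the source of the difference only. Whether labels were exchanged is not settled by it. The exchange would make these 8 targets higher in treated cells, but in 3 of 5 treated libraries only. The other 2 would keep a right RA label and levels like those of the exchanged ones (0 genes called between 2 h and 4 h). CYP26A1 had 0 counts in each library, so the RA targets alone do not settle it. Separate culture or preparation of the libraries labelled untreated cannot be told apart from the treatment, as the batch field has 1 value for all samples. The p53 activity in those cells may reflect handling or an agent that the labels do not name. Of the 56 splits of the 8 libraries into 5 and 3, 1 called as many genes, the real one with 7084, and the highest other called 0. An arbitrary split of these libraries therefore did not give such calls. Every other split mixes the groups by title, so the splits do not show what sets the groups apart. For 4 h against untreated the 10 splits are too few for a share under 0.05, with 7077 genes in the real split (1 of 10) and 0 in the highest other.

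Of 1209 genes with a genomic span over 150 kb, 50.5% were higher and 7.28% lower at 2 h, and 51.0% and 7.78% at 4 h, against 15.1% and 21.7% (2 h) and 19.7% and 21.1% (4 h) of 1816 genes under 5 kb. Over single libraries the trend overlapped: the rank correlation with span of a library's level relative to the untreated mean, itself left out, was 0.063 to 0.226 for those labelled RA, lowest in RA 4 h replicate 3, and -0.076 to 0.075 for those labelled untreated. Given exon length, GC content and mean level, the partial rank correlation with span at 4 h was 0.225 across 13015 genes. Transcript length or GC content therefore did not account for the trend as far as these ranks capture them, which does not exclude them in other forms. The rank correlation of the fold change with GC content was 0.074 at 2 h and 0.179 at 4 h, the latter above that with span. A candidate explanation is slower transcription through long genes in the libraries labelled untreated, with a rank correlation of 0.202 at 2 h and 0.146 at 4 h, where at least 0.2 was asked for. It stays open, as over 5 equal groups of genes by level the correlation ranged from 0.028 to 0.365 at 2 h and from 0.00098 to 0.308 at 4 h.

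The 2 RA libraries numbered 3 in the count table detected fewer genes. Sequencing depth does not account for it: after thinning to one total the lower of them still had 12.7% fewer genes than the lowest other RA library (13942 against 15978). Fewer distinct molecules before amplification may explain it, since the share of undetected genes implied 7.51 reads per molecule at 2 h and 4.10 at 4 h. The estimate was also 2.92 to 3.06 in the other RA libraries, above the 1.5 that the test allowed, and 2.43 to 2.79 in the untreated libraries, so the explanation stays open. No biological explanation was tested for it.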
